A study of Mus musculus with 2 samples.

How the data were processed

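Small RNA of fetal mouse liver (strain B6/129, embryonic day 18.5) was sequenced from 1 wild type library and 1 library of mice whose Argonaute 2 is catalytically inactive (Ago2ADH). Per the labels' protocols, total RNA was separated on a polyacrylamide gel to obtain a fraction of 19 to 30 nt. Adapters were then ligated, and the product was amplified by RT-PCR and sequenced on an Illumina GA2. Genotypes were taken from the labels of each sample.

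The authors deposited raw read counts, 1 count per distinct read sequence and library, with no normalization. Per the file headers, each sequence carries its number of genome matches, 1 annotation class and 1 name. The table holds 2344366 distinct sequences of 15 to 34 nt, and 0 of them are listed more than once. The aligner, the genome build, the annotation versions and the adapter trimming are not given in the sources used here. The table holds 0 columns of per-sample values from other samples. Because sequences were amplified by PCR and carry no molecular identifier, all counting intervals and floors below cover counting error only.

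Reads of the miRNA class (12128 distinct sequences under 597 names) were placed by exact match on the 1174 miRNA hairpins of GENCODE release M21 (GRCm38). A hairpin was found for 99.8% of the miRNA reads in wild type and 99.9% in Ago2ADH. The arm (5p or 3p) was set by whether the middle of the read lay before or after the middle of the hairpin. It was the arm in the authors' name for 99.96% of the reads whose name gives one. The unit of analysis was the arm of a named miRNA, so copies of a miRNA at several loci were summed. Names are those of the deposited table. Across both libraries, 88.2% of the miRNA reads match the genome once.

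Counts were scaled to the total of miRNA reads. The log2 ratio of Ago2ADH to wild type has an exact conditional binomial 95% interval, and shares have exact Clopper-Pearson 95% intervals. A library at 0 was given as a bound from 3 counts. With 1 library per genotype, the ratios have no replicate check and no p-value was computed for any of them. The only p-values are those of a closing permutation that compares hairpins with one another by their pairing. A size rule was used instead: an arm with 100 or more reads in both libraries together was called lower or higher when its ratio was 0.5 or less, or 2 or more, and its interval excluded 1. The words rose and fell are used for arms that met this rule.

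Lists of miRNAs for cell types, genomic clusters and families were fixed before the data were examined. Members with 50 or more reads entered, and a list's median was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries. For each of 214 hairpin names with 200 or more reads and reads on both arms, the minor arm was the one with fewer reads over both libraries. Its log2 odds were compared with 0.5 added to each count and a Woolf interval.

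The genes named were also chosen by a rule fixed beforehand. It takes every arm of miR-451 and miR-144 and the 12 arms with most reads in wild type. It adds up to 10 of the largest decreases and 10 of the largest increases under the size rule. The 4 members with most reads come from each list, with the 5 hairpins of largest rise and the 5 of largest fall of the minor-arm odds among those whose interval excludes 0. Other miRNAs named are those that met the size rule or lost it under another scaling. The mRNAs named, apart from Ago2, were picked after their values were seen. Fragments of mRNAs in the same table were scaled to all reads. They served as a measure of cell types, with marker lists written before their values were seen, and for Ago2 and the closing observations. These are short pieces of mRNAs, so their counts may change with mRNA breakdown as well as with mRNA level, which was not tested.

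The size rule was tested on simulated counts of 652 arms drawn at the real library sizes, with 200 arms changed. Scaled by the unchanged arms, it called 100% of the 20 testable arms at a ratio of 0.25, of the 23 at 0.333, of the 31 at 3 and of the 32 at 4. It called 0% of the 250 unchanged ones. No change near the 2-fold limit was simulated, so sensitivity there is unknown. The real calls were scaled to the total of miRNA reads instead, so these rates do not cover errors from that scaling. The arm comparison called 88% of 50 hairpins with odds raised 4-fold and 4.88% of 164 unchanged ones. Both simulations held counting noise only, without differences between animals or library preparations. Their rates on unchanged arms and hairpins therefore do not cover false calls from such differences.

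Alternatives were other scalings (all reads, median-of-ratios, TMM by edgeR 4.0.16, totals without the 10 most abundant miRNAs), reads of 20 to 24 nt, distinct sequences, other read minimums and other fold limits. Totals without the 10 most abundant miRNAs left out every arm among the 10 with most reads in either library, so more than 10 arms in all. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and Biopython 1.88, R 4.3.3, ViennaRNA 2.7.2 for duplexes and matplotlib 3.10.9 for plots.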

Results

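Small RNAs from late fetal mouse liver were profiled to compare wild type animals with animals carrying Ago2ADH, an Argonaute 2 without slicing activity. Argonaute 2 is the mammalian Argonaute that cleaves RNA paired to its small RNA guide. At this stage the liver holds hepatocytes together with blood-forming cells, most of them erythroid. There was 1 library per genotype, so no difference below has a replicate check. The wild type library held 7599870 reads of 1372123 distinct sequences, and the Ago2ADH library 7046197 reads of 1187672 distinct sequences. Of these, 2808232 and 2811227 were miRNA reads, so that 3 reads correspond to 1.07 RPM (reads scaled to the miRNA total) in either library.

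The targeted gene was looked at first. Ago2 lies on chromosome 15 (GRCm38, 73095844 to 73184935, minus strand). Fragments of its mRNA, listed under the older symbol Eif2c2, numbered 229 in wild type and 318 in Ago2ADH, a log2 ratio of 0.58 (95% interval 0.33 to 0.83) when scaled to all reads. The first catalytic aspartate codon was covered in Ago2ADH by 2 reads of 1 sequence, TGTCATCTTCCTGGGAGCCGCTG, which encodes D598A (residues counted from 1 at the start methionine of the 860-residue mouse protein). In wild type the codon was covered by 0 reads, so the check rests on those 2 reads.

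Both libraries were dominated by 22-nt reads and by miRNAs. miRNAs made up 36.95% of wild type reads (95% interval 36.92 to 36.99) and 39.9% of Ago2ADH reads (39.9 to 39.9). Fragments of RefSeq transcripts made up 12.7% and 12.01%, and repeat-track sequences 15.02% and 14.7%, of which tRNA fragments were 7.75% and 7.05% of all reads. Sequences in no class made up 28.8% and 27.9%. Reads of 26 nt were 2.04% of miRNA reads in wild type and 0.104% in Ago2ADH, and reads of 29 nt 0.179% and 0.00448%. Synthetic sequences made up 3.03% of wild type and 1.91% of Ago2ADH reads.

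The central comparison asked how loss of slicing affects miR-451, an erythroid miRNA whose hairpin is processed by Argonaute 2 in place of Dicer. miR-451-5p fell from 326892 reads in wild type, 11.6% of all miRNA reads, to 4373 reads in Ago2ADH, 0.156%. This was a 74.8-fold decrease (95% interval 72.6 to 77.1), a log2 ratio of -6.23. miR-144, which is encoded beside miR-451 and needs Dicer, went the other way: miR-144-3p rose from 10046 to 24407 reads, a log2 ratio of 1.28 (1.25 to 1.31). miR-144-5p, its minor arm, had 359 and 291 reads, a log2 ratio of -0.30 (-0.53 to -0.08). The few reads from the 3′ side of the mir-451 hairpin numbered 894 and 1048, a log2 ratio of 0.23 (0.10 to 0.36). This value is unstable: it was 1.28 with reads of 20 to 24 nt, 1.08 with only reads of 1 genome match, and 0.0264 without the 10 most abundant miRNAs in the total. The hairpins lie on the plus strand of chromosome 11 (GRCm38), Mir144 at 78073005 to 78073070 and Mir451a at 78073170 to 78073241, 99 nt apart. No annotated gene other than the antisense hairpin Mir451b overlaps them.

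**Figure D1:**
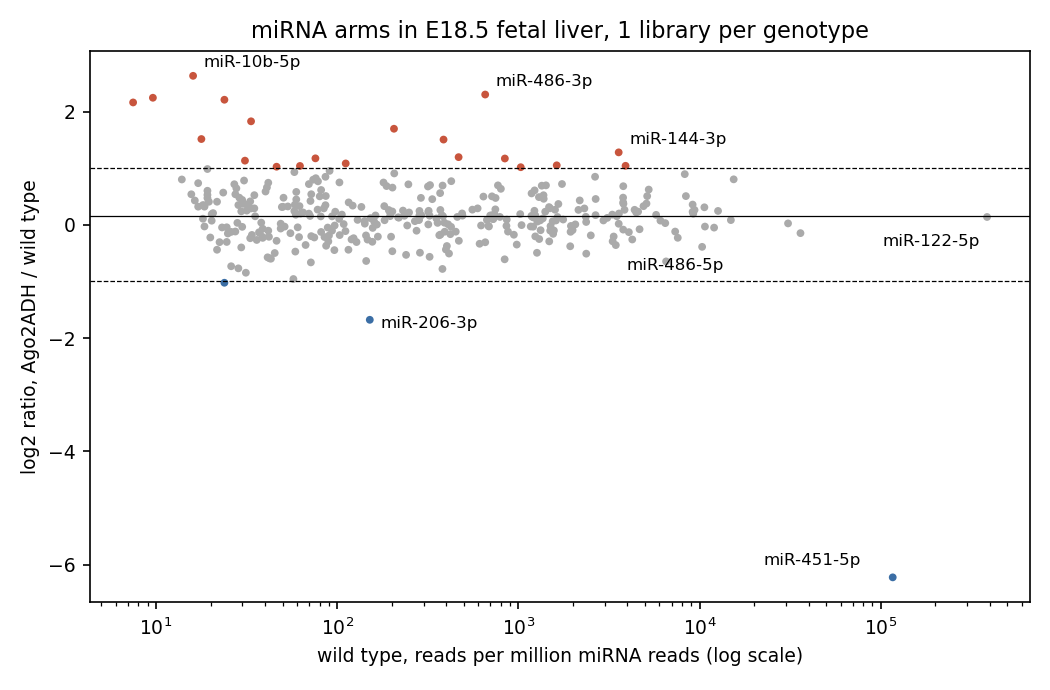
Each point is 1 miRNA arm with 100 or more reads, with its wild type level in RPM (log axis) against its log2 ratio of Ago2ADH to wild type. Blue and red points met the size rule as lower and higher, dashed lines mark 2-fold, and the solid line is the median of 0.15. miR-451-5p lies at -6.23 and the next lowest arm, miR-206-3p, at -1.68.

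Among 361 miRNA arms with 100 or more reads, 3 fell, 20 rose and 338 did not meet the size rule. Besides miR-451-5p, the muscle miRNA miR-206-3p fell from 425 reads in wild type, a log2 ratio of -1.68 (-1.97 to -1.39). miR-709-3p fell from 67 to 33 reads (-1.02, interval -1.67 to -0.40). With only reads of 20 to 24 nt miR-709-3p reversed to 1.52, but fewer than 100 reads were left, under the minimum of the size rule. The largest rise was that of miR-10b-5p, from 45 to 279 reads (2.63, interval 2.17 to 3.12). miR-486-3p, the minor arm of an erythroid miRNA encoded in an intron of Ank1, rose from 1842 to 9083 reads (2.30, interval 2.23 to 2.37). Rises were also measured for miR-193-3p (2.24), miR-141-3p (2.21), miR-33-5p (2.16), miR-21-3p (1.83), miR-136-5p (1.70), miR-297a-5p (1.51) and miR-29b-3p (1.51). Of these, miR-33-5p had fewer than 100 reads left when only reads of 20 to 24 nt were used, and there its log2 ratio was 2.35; miR-297a-5p has no read with 1 genome match.

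Loss of miR-451 alone raises the share of every other miRNA by 0.18 on the log2 scale, and the median log2 ratio over the 361 arms was 0.15. With median-of-ratios scaling, which sets that median to 0, 4 arms were lower and 13 higher, and those 13 were all among the 20. The 7 no longer called were let-7i-3p, miR-101a-3p, miR-210-3p, miR-376a-3p, miR-503-5p, miR-669b-5p and miR-671-5p. Totals without the 10 most abundant miRNAs of either library gave 5 lower and 10 higher, with miR-299-3p, miR-32-5p and miR-324-5p also no longer called.

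Apart from miR-451-5p, none of the most abundant miRNAs met the size rule. miR-122-5p, the main hepatocyte miRNA (Mir122, chromosome 18, 65248861 to 65248926, within an exon of a long noncoding RNA), took 38.6% of wild type and 42.5% of Ago2ADH miRNA reads, a log2 ratio of 0.14 (0.13 to 0.14) that is -0.0128 with median-of-ratios scaling. miR-16-5p was at -0.15, miR-22-3p at 0.02, miR-194-5p at 0.08, miR-103-3p at -0.05, miR-127-3p at -0.03, miR-541-5p at 0.24, miR-126-3p at 0.26 and miR-130a-3p at 0.31; miR-22-3p and miR-194-5p change sign with median-of-ratios scaling, and miR-103-3p and miR-127-3p when scaled to all reads. The outermost of the 12 most abundant arms, apart from miR-451-5p, were miR-21-5p at 0.80 (0.79 to 0.82) and let-7a-5p at -0.39 (-0.41 to -0.36).

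Erythroid miRNAs did not move as a group. Of 17 erythroid arms, miR-451-5p fell, while miR-144-3p, miR-486-3p and miR-210-3p rose. The list median was 0.06 (-0.0882 with median-of-ratios scaling), at the 11.3th percentile of random lists, and it was also 0.06 without miR-451. miR-16-5p and miR-22-3p, the most abundant of the others, did not meet the rule. Fragments of erythroid mRNAs were lower in Ago2ADH, with a median log2 ratio of -0.37 (interval of the median -0.57 to -0.18; -0.28 when scaled to RefSeq reads) over 25 genes, and 13 of them lay below 0 beyond counting error against 1 above. Of the marker mRNAs, picked here and below after their values were seen, alpha globin Hba-a2 went from 9129 to 5225 reads (-0.70), beta globin Hbb-b2 from 3413 to 2106 (-0.59), and the red cell anion exchanger Slc4a1 from 645 to 392 (-0.61). The transferrin receptor Tfrc was the 1 gene above, with 178 and 229 reads (0.47).

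Hepatocyte miRNAs had a median of 0.29 (83.0th percentile), and 2 of 14 arms rose, miR-193-3p and miR-101a-3p. miR-101b-3p was at 0.89 and miR-192-5p at 0.51. Hepatocyte mRNA fragments had a median log2 ratio of -0.0798 over 30 genes, which turns to 0.00572 when scaled to RefSeq reads. Of these genes, 14 lay below 0 beyond counting error and 5 above. Albumin (Alb) was at -0.04, and above 0 when scaled to RefSeq reads. Values were, for the fibrinogen chains Fga and Fgb, -0.26 and -0.39, for transferrin (Trf) 0.32 and for alpha-fetoprotein (Afp) 0.29.

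Of the lists for other cell types, none of the 14 white blood cell arms met the rule. Their median was 0.11 (35.03th percentile; -0.0362 with median-of-ratios scaling), with miR-223-3p at -0.12, miR-142-3p at 0.85 and miR-142-5p at 0.43. miR-181a-5p was at 0.18, and below 0 without the 10 most abundant miRNAs in the total. Myeloid mRNA fragments had a median of -0.0667 over 10 genes, which turns to 0.0189 when scaled to RefSeq reads. Endothelial and stromal miRNAs had a median of 0.16 (50.6th percentile; -0.0440 without the 10 most abundant miRNAs in the total), and miR-10b-5p was the 1 of 11 that rose. miR-126-5p was at 0.70, miR-143-3p at 0.20 and miR-145-5p at 0.16, the last 2 below 0 without the 10 most abundant miRNAs in the total. Endothelial and stellate mRNA fragments had a median of -0.52 over 7 genes, with an interval of -1.04 to 0.31.

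Muscle miRNAs had a median of -0.37, at the 1.09th percentile, over 5 arms, and of 0.00465 with a minimum of 500 reads. miR-206-3p fell, while miR-1-3p was at -0.37, miR-133a-3p at 0.17 and miR-499-5p at 0.00465, the last 2 below 0 without the 10 most abundant miRNAs in the total. These are scarce in liver, with 457 wild type reads for miR-133a-3p. Epithelial miRNAs had a median of 0.31 (83.7th percentile), and 1 of 11 arms, miR-141-3p, rose. miR-200a-3p was at 0.72, miR-429-3p at 0.31, miR-375-3p at 0.27 and miR-200b-3p at 0.09, the last below 0 with median-of-ratios scaling. No neural arm of 5 met the rule (median 0.25, 81.1th percentile), with miR-124-3p at 0.25, miR-9-3p at 0.59, miR-128-3p at 0.11 and miR-9-5p at 0.16, the last 2 below 0 without the 10 most abundant miRNAs in the total.

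**Figure D2:**
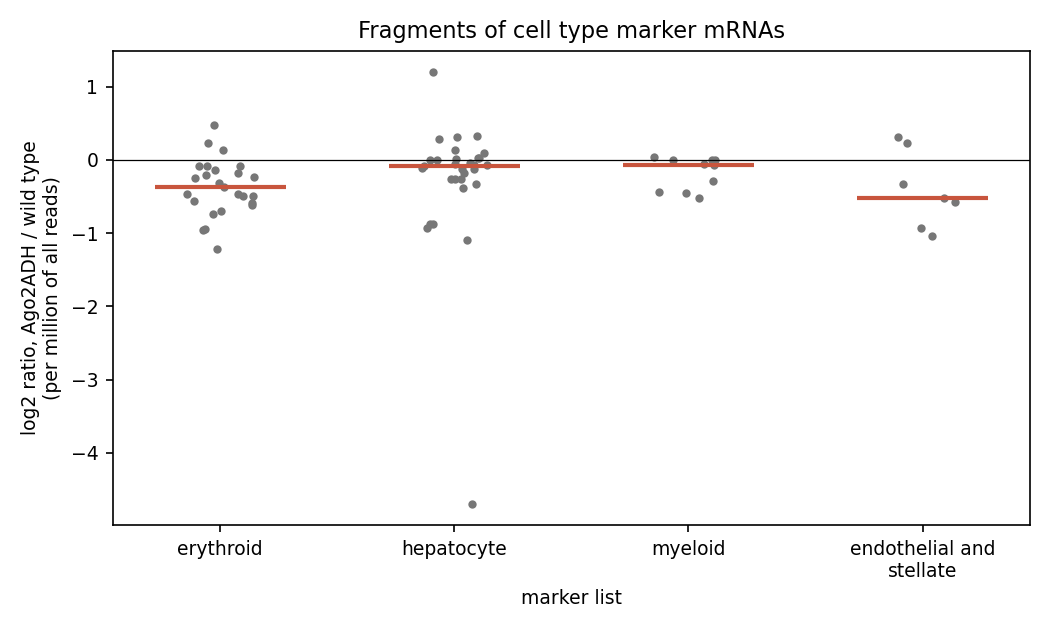
Each point is the log2 ratio of Ago2ADH to wild type, scaled to all reads, for fragments of 1 marker mRNA with 50 or more reads, and red bars are list medians. The medians are -0.37 for erythroid, -0.0798 for hepatocyte, -0.0667 for myeloid and -0.52 for endothelial and stellate genes, of which the hepatocyte and myeloid medians turn above 0 when scaled to RefSeq reads; the lowest hepatocyte point is Serpina1e at -4.70.

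Among genomic clusters, the Sfmbt2 cluster, a large imprinted rodent cluster, stood highest. Its median was 0.54 (interval of the median 0.36 to 1.03), at the 99.5th percentile of random lists. miR-297a-5p and miR-669b-5p rose, neither of them with any read of 1 genome match, and 12 of its 13 arms with 100 or more reads lay above 0. Its most abundant arms were miR-669a-5p at 0.32, miR-467e-5p at 0.51, miR-467d-5p at 0.50 and miR-669c-5p at 0.54. Its members are near-identical copies, so reads shared between them cannot be told apart. Of 84 arms of the imprinted Dlk1-Dio3 cluster, 3 rose (miR-136-5p, miR-299-3p and miR-376a-3p, the last 2 not called without the 10 most abundant miRNAs in the total), and the median was 0.11 (17.99th percentile; -0.0429 with median-of-ratios scaling). miR-376b-3p was at 0.20, below 0 without the 10 most abundant miRNAs in the total, and miR-369-3p at 0.62.

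The let-7 family had a median of 0.17 over 14 arms (49.65th percentile; -0.0355 without the 10 most abundant miRNAs in the total). let-7i-3p rose, and let-7c-5p was at 0.22, let-7g-5p at 0.03 and let-7f-5p at 0.07, the last 2 below 0 with median-of-ratios scaling. miR-17-92 and its paralogs had a median of 0.05 over 20 arms (11.15th percentile; -0.106 with median-of-ratios scaling), and 0 met the rule, with miR-20a-5p at 0.36, miR-92a-3p at 0.38, miR-18a-5p at 0.48 and miR-93-5p at -0.23. Hairpins that bypass the Microprocessor had a median of 0.41 over 3 arms (84.1th percentile), with miR-320-3p at 0.29, miR-484-5p at 0.47 and miR-877-5p at 0.41. The imprinted fetal growth miRNAs had a median of 0.14 over 9 arms (55.7th percentile; -0.0120 with median-of-ratios scaling), with miR-483-3p at 0.61, miR-483-5p at -0.20, and miR-335-5p at 0.06 and miR-298-5p at 0.14, the last 2 below 0 with median-of-ratios scaling.

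The share of the minor arm was compared because slicing can remove the passenger strand of a duplex. Over the hairpin names with reads on both arms there was no general gain of minor arms in Ago2ADH. The median log2 odds ratio was -0.17 (interval of the median -0.27 to -0.01), and the share was higher beyond counting error for 37, lower for 47 and within it for 130. The median share was 2.30% in wild type and 2.01% in Ago2ADH.

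A few hairpins shifted strongly. For miR-486 the 3p share rose from 15.98% (15.3 to 16.7) to 54.6% (53.8 to 55.3), so that it became the larger arm among the reads counted. Meanwhile miR-486-5p had 9684 and 7562 reads (-0.36, interval -0.40 to -0.31). Reads with an extra 3′ nucleotide that the genome does not encode, frequent for miR-486-5p, were not counted. The arm comparison was not run with them, so which arm is larger with such reads is unknown. When only reads with 1 genome match were kept, miR-486-5p met the size rule as lower. Its main 3p read, CGGGGCAGCTCAGTACAGGAT, had 979 and 5506 reads. Mir486 lies on chromosome 8 (GRCm38, 23142555 to 23142682, plus strand) in an intron of Ank1, with Mir3107 on the opposite strand, and the 5p read TCCTGTACTGAGCTGCCCCGA matches both hairpins. The share from the 3′ side of mir-451 rose from 0.273% to 19.3%, mostly through loss of the 5′ product. These 3′-side reads include some that overlap the 5′ product. The share also rose for miR-33-5p (28.8% to 59.1%), miR-299-3p (27.0% to 54.4%) and miR-193-3p (26.0% to 53.3%). It fell for miR-144-5p (3.45% to 1.18%), miR-301a-5p (0.870% to 0.199%), miR-133a-5p (2.56% to 0.774%), miR-193b-5p (5.69% to 1.77%) and miR-32-3p (6.99% to 2.83%). Of the last 4, none had more than 19 minor-arm reads in a library.

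**Figure D3:**
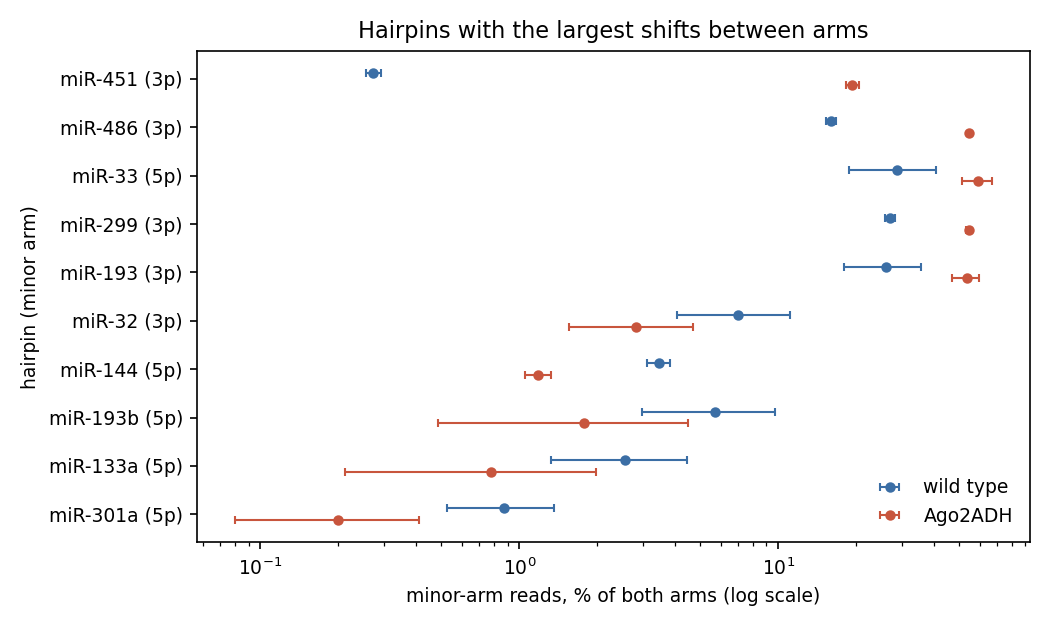
Minor-arm reads as a percent of both arms (log axis) for the 5 hairpins with the largest rise and the 5 with the largest fall of its odds among those beyond counting error, wild type in blue and Ago2ADH in red, with exact 95% counting intervals. The miR-486-3p share goes from 15.98% to 54.6% and the miR-144-5p share from 3.45% to 1.18%. Reads with an extra 3′ nucleotide that the genome does not encode are not counted.

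The ends of the remaining miR-451 reads differed between the genotypes. Most hairpin reads started at hairpin position 17 (chromosome 11, 78073186), 91.96% in wild type and 74.5% in Ago2ADH. In wild type, 52.9% (52.7 to 53.0) of these ended at position 39, giving the 23-nt AAACCGTTACCATTACTGAGTTT, and 34.0% were 25 to 30 nt long. In Ago2ADH, 45.3% (43.8 to 46.9) ended at position 36, giving the 20-nt AAACCGTTACCATTACTGAG, against 0.414% (0.391 to 0.438) in wild type. Only 34.3% ended at position 39 and 8.19% were 25 to 30 nt long.

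The 20-nt product was not depleted, with 1248 reads in wild type and 1831 in Ago2ADH, a log2 ratio of 0.55 (0.45 to 0.66). Reads that ended at position 39 or later had a log2 ratio of -7.27. The fold decrease was 115 for ends at 39, 182.2 at 40, 269 at 41, 342 at 42, 155.2 at 43 and 550 at 45, the last from 9 reads in Ago2ADH (log2 interval -10.23 to -8.18). The 28-nt and 30-nt reads had 319 and 236 counts in wild type and 0 in Ago2ADH, which allows up to 0.0742% of its 4041 reads; the 30-nt read was at least 78.8-fold lower. Reads starting at position 37, directly after the 20-nt product, were higher in Ago2ADH, from 98 in wild type (log2 ratio 1.75, interval 1.42 to 2.09). Their main form was TTTAGTAATGGTAACGGTTCT (positions 37 to 57, chromosome 11, 78073206 to 78073226), with 68 and 233 reads.

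**Figure D4:**
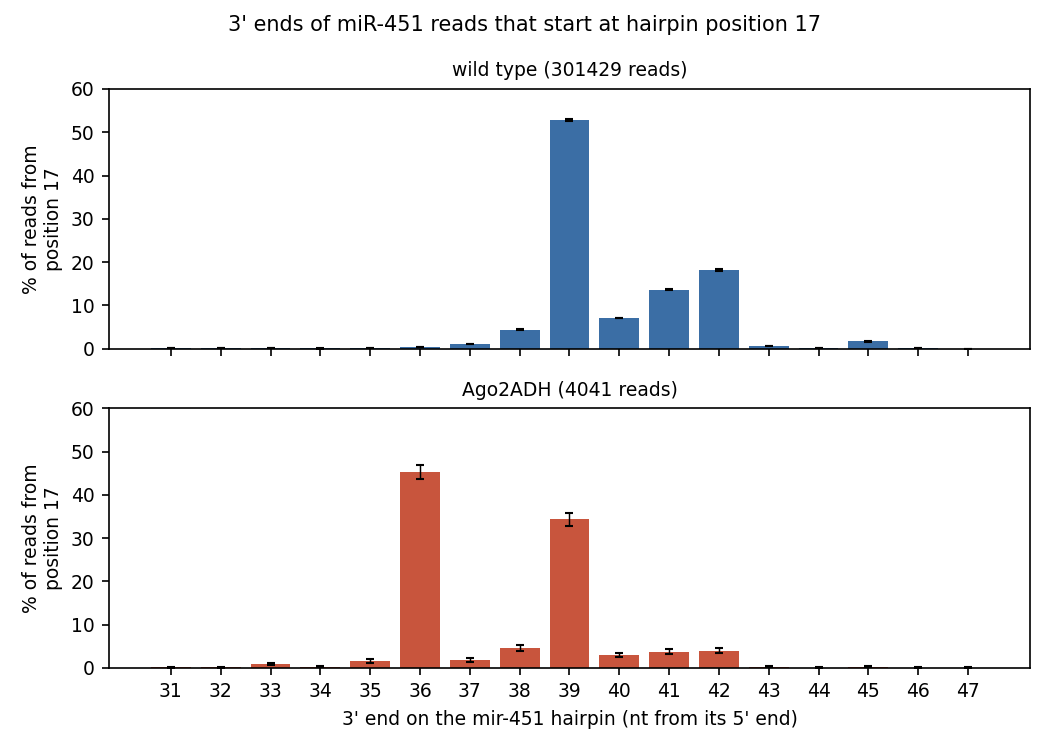
Percent of miR-451 reads starting at hairpin position 17 by the position of their 3′ end, in wild type (301429 reads) and Ago2ADH (4041 reads), with exact 95% counting intervals. The wild type peak at position 39 holds 52.9% of reads, and the Ago2ADH peak at position 36 holds 45.3%.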

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

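The tests of miR-486-5p, of erythroid mRNAs against miR-144-3p and of the miR-451 read ends were chosen after those results were seen; the others were set before.

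Outside the miRNA class, some signals were higher in Ago2ADH than in wild type and were named by limits chosen after their values were seen. Fragments of the U5 spliceosomal RNA had 12039 and 28428 reads, a log2 ratio of 1.35 when scaled to all reads. Fragments of tRNA-Arg-CGG had 552 and 1068 reads, a log2 ratio of 1.06. Reads of miR-15a-5p with 1 extra 3′ U that the genome does not encode made up 9.26% of that miRNA in wild type and 16.5% in Ago2ADH. For miR-486-5p with 1 extra 3′ C the shares were 8.43% and 15.3%.

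miR-451-5p fell by 6.23 on the log2 scale while miR-144-3p, from the neighbouring hairpin, rose by 1.28. Fewer erythroid cells would lower fragments of erythroid mRNAs by a like amount, but their median log2 ratio was -0.37. Taken as a measure of cells, this argues against fewer erythroid cells as the main cause of the loss. The same median of -0.37 argues against more erythroid cells as the cause of the miR-144-3p rise. The trend of the log2 ratio on GC content was flat (Spearman -0.0472 over 359 arms), so removing it shifts all arms nearly alike, to -6.45 and 1.05 here, and GC content was left untested. A difference between single animals or litters stays open because each genotype has 1 library; the genotype itself, through slicing of the mir-451 hairpin, may be the cause of the miR-451 loss, and is untested here.

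The miR-451 reads left in Ago2ADH could be wild type reads carried over between libraries. Carry-over keeps the wild type proportions of ends, but 45.3% of reads from the main 5′ end stopped at position 36, against 0.414% in wild type. Among reads ending at position 39 or later, 75.6% ended at 39 against 56.2% in wild type, so carry-over does not explain these alone either. The 29-nt reads allow a carry-over that gives up to 25.8% of the Ago2ADH reads from the main 5′ end, so a part of them stays open. That the 20-nt read and the read starting at position 37 come from another cleavage of the same hairpin between positions 36 and 37 is a hypothesis with no test here.

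miR-486-3p rose by 2.30 on the log2 scale. With the same flat GC trend removed the value was 2.14, which tests nothing. More transcription of the locus or more erythroid cells would raise both arms, but miR-486-5p was at -0.36. The 5p read most frequent over both libraries also matches the antisense copy, and the source of those reads cannot be told. With only reads of 1 genome match, miR-486-5p met the size rule as lower. Fragments of the host gene Ank1 were at -0.14 scaled to all reads, within counting error of 0 (-0.43 to 0.14). A candidate explanation is that the 3p strand is normally cleaved by Argonaute 2 as a passenger strand, which stays a hypothesis from 1 library per genotype.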

How the results depend on the processing

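The restriction to reads with 1 genome match, the inclusion of reads with 1 extra 3′ nucleotide, the RefSeq scaling of mRNA fragments and the erythroid list without miR-451 were chosen after the data were seen. Each sequence has 1 miRNA name, so the planned restriction to reads with 1 name changes nothing and was not run. miR-451 stayed below and miR-144-3p above wild type in all alternatives run. The miR-451 and miR-144-3p log2 ratios were -6.11 and 1.39 scaled to all reads, -6.38 and 1.13 with median-of-ratios scaling, -6.37 and 1.14 with TMM, -6.43 and 1.08 without the 10 most abundant miRNAs in the total, and -5.88 and 1.32 with reads of 20 to 24 nt. Counting distinct sequences, which ignores abundance, gave -0.92 and 0.26, with 0 arms lower and 0 higher. miR-709-3p reversed with reads of 20 to 24 nt, to 1.52; the cause was not tested.

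Against 3 lower and 20 higher arms, scaling to all reads gave 2 lower and 25 higher, with miR-709-3p no longer called lower. Median-of-ratios and TMM each gave 4 lower and 13 higher, and totals without the 10 most abundant of either library 5 and 10. Reads of 20 to 24 nt gave 3 lower and 16 higher. Only reads with 1 genome match gave 3 and 18, and including reads with 1 extra 3′ nucleotide gave 4 and 20. A minimum of 20 reads gave 7 and 33 and a minimum of 500 reads 12 higher, through the arms admitted. A limit of 1.5-fold gave 14 and 59, and 3-fold gave 7 higher.

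List medians moved with scaling, which shifts all arms alike. In the order all reads, median-of-ratios, TMM and without the 10 most abundant, the Dlk1-Dio3 median was 0.22, -0.0429, -0.0351 and -0.0934, and the median of Microprocessor-independent hairpins 0.52, 0.26, 0.27 and 0.21. The neural median was 0.0943, 0.10 and 0.0438 in the last 3, and the Sfmbt2 median 0.34 in the last. With distinct sequences the neural median was 0.0396, that of Microprocessor-independent hairpins 0.0396 and that of the Sfmbt2 cluster 0.23.

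The miRNA share in wild type and Ago2ADH was 0.698% and 0.784% of distinct sequences, 42.1% and 45.1% of reads of 19 to 30 nt, and 43.1% and 45.6% of reads from sequences with 2 or more reads. The minor-arm median and counts stayed within their intervals or 1.5-fold. Of all mir-451 hairpin reads, 0.401% ended at position 36 and 52.3% at 39 in wild type, and 35.3% and 27.5% in Ago2ADH. From the main 5′ end only, the share at 39 was 52.9% in wild type, and in Ago2ADH 45.3% ended at 36 and 34.3% at 39. Over distinct sequences the shares at 36 and 39 were 3.31% and 5.52% in wild type, and 4.55% and 6.06% in Ago2ADH. Depth limits the scarce arms: miR-33-5p had 21 reads in wild type, miR-193-3p 27 and miR-10b-5p 45.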

Other observations

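The lists below were chosen after some of their members had been seen, but the test of other hypoxia targets was set before their values were seen. The pairing test was set after the arm odds had been seen and before any pairing was computed.

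Fragments of mRNAs that are targets of hypoxia-inducible factor were higher in Ago2ADH. Fragments of the glycogen enzymes Gys1 (log2 ratio 0.81) and Gbe1 (0.81), of Ndrg1 (0.80), Bsg (0.71), Igfbp1 (0.61) and Gapdh (0.61) were noticed first, beside miR-210-3p, a hypoxia-induced miRNA, at 1.05. A transcriptional response to low oxygen was then tested as a hypothesis on 52 other known targets, of which 38 had 50 or more reads. Of these, 37 lay above 0 and 21 did so beyond counting error, against 0 below. Their median was 0.47 (interval of the median 0.26 to 0.69), at percentile 100 of 10000 random transcript lists matched on mean reads. Members with higher values included Ddit4 (1.18), the oxygen sensor Egln3 (1.17), Ak3l1 (1.04) and Vegfa (0.999). Glycolysis genes ranged from Gpi1 at 0.96 to Aldoa at 0.30, Pkm2 at 0.25 and Pgam1 at 0.24, these last 3 within counting error of 0, while the glucose transporter Slc2a1 was at 0.06 and the haem oxygenase Hmox1 at -0.20. The data may reflect low oxygen in the Ago2ADH fetus or a delay before this tissue was taken, and 1 library per genotype cannot separate them.

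Fragments of the host gene Sfmbt2 had a log2 ratio of 0.57 scaled to all reads; the median of its miRNA cluster was 0.65 on that scale and 0.54 scaled to miRNA reads. Of 334 transcripts with 500 or more fragment reads, 0 were at least 2-fold higher in Ago2ADH and 3 were lower. These were Serpina1e (867 and 31 reads, -4.70), Slc29a3 (9124 and 2803, -1.59) and Serpina1d (562 and 244, -1.09). The Serpina1 genes are near-identical copies, so their counts are uncertain; Serpina1b was at -0.94, Serpina1a at -0.88 and Serpina1c at -0.87.

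An extra U was frequent on some long miR-451 reads in wild type and rare on the most abundant ones. The 30-nt form ending at hairpin position 46 had 236 reads as encoded and 1087 with 1 added U, which is 82.2% of these (95% interval 80.0 to 84.2). For the 27-nt form the share was 39.5%, for the abundant 26-nt form 2.02% and for the 29-nt form 2.87%. In Ago2ADH the 30-nt form had 0 reads as encoded and 3 with the added U. Over all miRNAs an added U was found on 4.66% of reads in wild type and 5.11% in Ago2ADH. For miR-486-5p the share with an added U was 42.3% in wild type and 28.8% in Ago2ADH, and the 22-nt form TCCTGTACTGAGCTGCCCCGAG had 4426 and 2117 reads (log2 ratio -1.07).

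A hypothesis was that duplexes with a fully paired guide keep more passenger strand without slicing. Guide positions 2 to 18 were fully paired to the minor arm in 11 of the hairpins, miR-486 among them. G-U pairs were accepted, and unpaired bases of the minor arm were not counted. The 11 include let-7a, let-7b, let-7f, let-7i and miR-98 of the let-7 family, and miR-27a with miR-27b. The permutation that follows treats these related hairpins as independent. let-7b had only 2 minor-arm reads in wild type and 0 in Ago2ADH. Without miR-486 and miR-451, the 10 others had a median log2 odds of 0.24 against -0.19 for 202 hairpins, a difference of 0.43 with a one-sided permutation p = 0.0695. With both included the p was 0.0336. The difference is in the predicted direction, but it does not pass 0.05 with both left out, so the hypothesis stays open.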
